A study of Saccharomyces cerevisiae with 31 samples.

How the data were processed

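Total RNA from a continuous, aerated culture of Saccharomyces cerevisiae CEN.PK122 was measured on 31 Affymetrix Yeast 2.0 arrays, 1 per time point, every 4 min from 12.53 to 14.53 h of a metabolic oscillation with a nominal period of 2 h. Per the labels, RNA was reverse transcribed from oligo(dT) primers, transcribed into biotinylated cRNA, fragmented, hybridized, stained and scanned by the standard Affymetrix procedure. The deposited values are probe set signal intensities on a linear scale, made with GCOS, the Affymetrix operating software, per the submitters' processing notes; its version, scaling target and mask are not given in the sources used here. Deposited intensities ran from 0.1 to 24502. The labels give each array a time and a phase angle, from 5.93 to 362.01 degrees, and form 1 group with no control samples; they name no test. They describe 1 time series, treated here as 1 culture. The number of arrays limits the precision.

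Of 10928 probe sets, 166 were array controls, 5498 had 1 gene symbol of S. cerevisiae, 1747 belonged to genes outside S. cerevisiae (the array also carries Schizosaccharomyces pombe), 1 of these to several genes, and 3517 had none, 47 of them reporter controls by their names. Gene names came from the annotation of the array and from a gene table for assembly R64 of S. cerevisiae S288C, which updated 12 symbols; the genome build behind the probe design was not stated. CEN.PK122 is another strain, so sequence differences from S288C can lower single probe sets. Where a gene had several probe sets (39 genes), the one with the highest median intensity stood for it.

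The rules for normalization, filters, tests, gene lists, named genes and most alternatives were fixed before the data were examined. Intensities were taken to log2. Array medians over S. cerevisiae probe sets differed 2.03-fold, from 1056 to 2142, which met the fixed rule (over 2-fold) for quantile normalization over these probe sets; values on the deposited scale became an alternative. Probe sets with a median intensity at or under 17.04, percentile 95 of the medians of probe sets outside S. cerevisiae, were left out (76), leaving 5422 for 5382 genes.

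Variation with phase was tested with limma 3.58.1 in R 4.3.3 by a fit on the cosine and sine of the labelled phase angle and a moderated F-test of both, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The peak-to-trough range and the peak angle come from both coefficients, with SEs from limma's moderated variance by the delta method. These SEs take the arrays as independent. A range of 1 on the log2 scale is 2-fold. Variation beyond 1 cosine per cycle, called faster variation here, was tested by a moderated F-test of the terms at 2 and 3 times the angle, beside the first harmonic. Peak angles were summarized by windows of 60 degrees and by the resultant length. For 22 gene lists the mean of centred log2 values per array was fitted in the same way, its F statistic was set against 100000 permutations of the arrays with adjustment over the lists, and its size was ranked among 10000 random lists matched on size and mean level. The lists cover ribosomal proteins, ribosome biogenesis, mitochondrial translation, central carbon metabolism, storage carbohydrates, sulfur and amino acid synthesis, peroxisomes, protein turnover, stress, cell division, ergosterol, hexose transport and early meiosis; 10 of them have members that were not measured. The first and last arrays were compared by value only, and odd and even arrays by separate fits. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

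The genes named are the 10 with the largest fitted range, the 3 with the largest range in each window of the peak angle, the 2 members of each list with the smallest p, the 10 with the largest range of the faster terms, and ACT1, TDH3, PMA1 and ADH2 as references. Other names were chosen after their values were seen and are marked so.

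The poly-A spike controls, set against the hybridization spikes, split the arrays into a batch of 16 (-3.83 to -3.21 on the log2 scale) and a batch of 15 (-4.89 to -4.37). The split follows the numbers in the array descriptions, whose meaning is not stated; it is called a labelling batch here. Fits with batch as a term and within each batch were added after the data were seen, as were scaling by the hybridization spikes, pre-whitening of the faster terms at 0.645 and a fit without the 5 dimmest arrays. The batches sampled different angles, with widest gaps of 71.2 and 59.3 degrees. Batch 1 held no array from 17.8 to 41.54 or from 100.88 to 148.35 degrees. Batch 2 held none from 53.41 to 89.01 or from 160.22 to 195.82 degrees. Values within a batch are therefore not replicate estimates over the whole cycle.

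The tests were checked on simulated data of the same size with 200 changed probe sets. With independent noise, 10 of 5222 flat probe sets (0.191%) passed, and 70%, 90%, 98% and 100% of 50 probe sets with simulated ranges of 0.25, 0.5, 1 and 2 were recovered. Serially correlated noise was then simulated at the autocorrelation of neighbouring arrays after the first harmonic (0.645). With it 46.7% of flat probe sets passed, 29 of them at 2-fold or more, and 12.8% after correction for that correlation (pre-whitening). The spread of this noise came from the fit of the first 3 harmonics, which left less variance than the first harmonic that gave the correlation. Noise as large as the residuals of the first harmonic was not simulated. Among 200 flat lists of independent noise, 4.5% had a permutation p under 0.05, which does not check that test under serial correlation. After the first 3 harmonics the residual autocorrelation was 0.0715, against -0.262 in the simulated independent noise and 0.046 in the simulated correlated noise, so this value does not show the correlation removed.

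Alternatives were the deposited scale, median centring, no filter, a stricter filter at percentile 40, a pseudocount of 32, a linear trend in time, the description number as a covariate, pre-whitening, an intensity trend with a robust prior, the first 3 harmonics together, odd or even arrays alone, a threshold of 0.01, each array left out in turn, and, as a negative control, the description number in place of the phase angle.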

Results

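Transcript levels were measured on 31 Affymetrix Yeast 2.0 arrays in a continuous, aerated culture of Saccharomyces cerevisiae CEN.PK122. Cells in such a culture can swing together between respiratory and reductive metabolism, which shows as a rhythm in dissolved oxygen, here with a period of 2 h. Total RNA was sampled every 4 min from 12.53 to 14.53 h, and each array carries a phase angle in its label, from 5.93 to 362.01 degrees. All arrays form 1 group with 1 array per angle. The labels do not say which angles were respiratory and which reductive, so phases are given here only as angles. The median deposited intensity of S. cerevisiae probe sets ran from 1056 to 2142 per array, and the number of arrays limits the precision of every value. The arrays come from 1 time series, treated as 1 culture, and 1 sampled cycle. The p-values therefore reflect the spread among these arrays around a fitted curve and show variation with phase, not recurrence. SEs of fitted ranges and peaks come from the same spread and take the arrays as independent. Residuals of neighbouring arrays were correlated (0.645 after the first harmonic), so these SEs may be too small.

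The first comparison asked which genes varied with the phase of the oscillation. AAH1, which encodes adenine deaminase, had the largest fitted peak-to-trough range, 4.04 ± 0.39 on the log2 scale (SE, n = 31 arrays), a 16.5-fold difference with a fitted peak at 0.35 ± 5.58 degrees (SE). Its normalized log2 intensity averaged 13.15 ± 0.35 (SD, n = 6 arrays) from 0 to 60 degrees and 8.71 ± 0.23 (SD, n = 5 arrays) from 120 to 180 degrees. The RNA helicase gene DBP2 and the ribosome assembly genes RIX1, RSA4 and MAK16 were high at nearly the same angles, with fitted ranges of 3.79 ± 0.37, 3.48 ± 0.36, 3.45 ± 0.39 and 3.42 ± 0.41 (SE). With fitted peaks on the opposite side of the cycle, FAT3, which acts in fatty acid uptake, varied by 3.78 ± 0.46, the stationary-phase survival gene SPG1 by 3.68 ± 0.41, the reticulon gene RTN2 by 3.61 ± 0.37 and the membrane heat shock gene HSP30 by 3.41 ± 0.26 (SE), at 218.0, 201.9, 195.7 and 193.4 degrees. The uncharacterized gene YNL162W-A completed the 10 largest ranges with 3.59 ± 0.45 at 358.8 degrees.

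Of 5422 probe sets tested, 4831 (89.1%) passed limma's moderated F-test at an adjusted p under 0.05, and 1253 of these (23.1% of those tested) had a fitted range of 2-fold or more. Adjusted p-values of the 10 genes with the largest ranges lay between 2.95e-11 for HSP30 and 1.75e-07 for YNL162W-A. The median fitted range of the probe sets that passed was 0.60 on the log2 scale. Within each of the labelling batches that the poly-A spikes set apart, of 16 and 15 arrays, 4178 and 4510 probe sets passed, 913 and 1731 of them with ranges of 2-fold or more. Of the 1253 with 2-fold ranges over all arrays, 1229 and 1240 passed within the batches. The batches sampled different angles, so counts and ranges within them are not replicates of each other. The overall count depended on how noise was modelled: 2919 probe sets passed when neighbouring arrays were treated as serially correlated, but 1174 of the 1253 with 2-fold ranges still passed.

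The reference genes differed. ACT1, which encodes actin, had a fitted range of 0.05 ± 0.03 (SE, adjusted p = 0.200, limma), and TDH3, a gene for glyceraldehyde-3-phosphate dehydrogenase, of 0.05 ± 0.04 (SE, adjusted p = 0.474, limma). Neither passed, although median centring of the arrays gave ranges of 0.33 for ACT1 and 0.32 for TDH3 with adjusted p-values of 0.00223 and 0.0133, within ranges over all alternatives of 0.00223 to 0.841 and 0.0133 to 0.941. The normalized intensity of ACT1 stayed between 14543 and 16809, near the top of the scale, since the highest deposited intensity was 24502. PMA1, which encodes the plasma membrane proton pump, varied by 0.35 ± 0.04 (SE, adjusted p = 8.3e-08, limma) with a fitted peak at 9.7 degrees, and the alcohol dehydrogenase gene ADH2 by 0.72 ± 0.14 (SE, adjusted p = 9.08e-05, limma) with a fitted peak at 238.0 degrees.

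**Figure D1:**
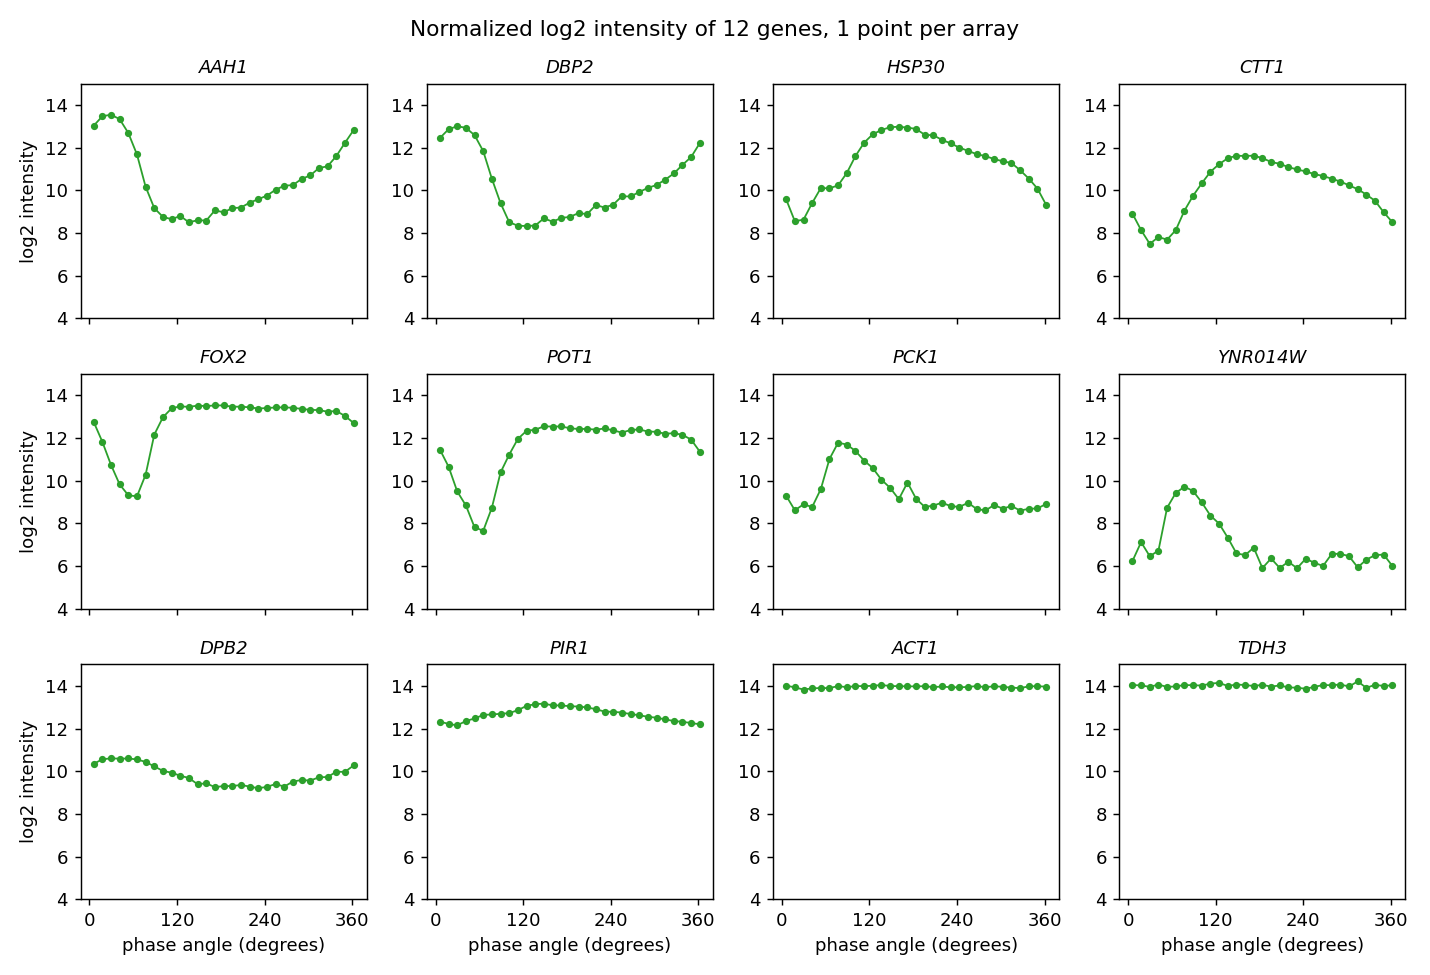
Normalized log2 intensity (vertical axis) of 12 genes against the phase angle in degrees (horizontal axis), with 1 point for each of the 31 arrays. AAH1 and DBP2 were highest at 29.67 degrees, HSP30 at 160 and CTT1 at 172 degrees, FOX2 and POT1 were lowest at 65.28 degrees, PCK1 and YNR014W were highest at 77.14 degrees, DPB2 and PIR1 varied by 1.30 and 0.84 in fitted range, and ACT1 and TDH3 had fitted ranges of 0.05.

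The second comparison asked where in the cycle the peaks lay. With fitted peaks between 0 and 60 degrees AAH1, DBP2 and HAS1, another ribosome biogenesis helicase gene, had the largest ranges. From 60 to 120 degrees these were the uncharacterized YNR014W with 2.55 ± 0.38 (SE), the gluconeogenic gene PCK1 with 2.21 ± 0.31 and the hexose transporter gene HXT17 with 1.80 ± 0.38, of which HXT17 did not pass under the serially correlated model, where its range stayed at 1.77 (adjusted p = 0.140, range over all alternatives 0.000296 to 0.140). From 120 to 180 degrees they were YNL194C with 3.34 ± 0.44, the transcription factor gene USV1 with 3.30 ± 0.41 and FMP48 with 3.11 ± 0.35 (SE). FAT3, SPG1 and RTN2 led from 180 to 240 degrees. From 240 to 300 degrees the formate dehydrogenase gene FDH1 varied by 2.77 ± 0.32, the stress gene GRE1 by 2.61 ± 0.30 and the elongation factor gene HEF3 by 2.14 ± 0.28 (SE). YNL162W-A, RIX1 and RSA4 led from 300 to 360 degrees.

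Where the peaks fell depended on the curve fitted. In the 6 windows of 60 degrees from 0 upward, 1120, 360, 974, 1404, 168 and 805 of the probe sets that passed had their fitted peak, and 299, 17, 165, 426, 14 and 332 of those with 2-fold ranges. With the first 3 harmonics together, the highest point of the curve fell in the first 4 of these windows for 2015, 1271, 1244 and 363 of the 5188 probe sets that then passed, and in all 6 windows for 958, 491, 555, 70, 12 and 22 of the 2108 with 2-fold ranges in that fit. With this curve 60 to 120 degrees held more peaks than 180 to 240 degrees. With a linear trend in time beside the first harmonic the counts were 432, 269, 1811, 552, 146 and 1517. Over 1 sampled cycle time rises with the angle, so such a trend can take up part of the variation with phase. The fitted peak of the first harmonic marks the centre of the high part of a profile, not its highest array: SPG1 was highest at 136 degrees against a fitted 201.9 degrees. The resultant length of the peak angles, which runs from 0 for evenly spread angles to 1 for a single angle, was 0.087, and 0.512 for doubled angles. The share of probe sets peaking from 300 to 60 degrees was 39.8% here, 62.2% on the deposited scale, 46.2% when scaled by the hybridization spikes and 37.4% with median centring, and the resultant length was 0.445 and 0.370 on the deposited and spike scales. Array medians on the deposited scale spanned 1.01 on the log2 scale, and ranges and peaks here are relative to those medians. Within the batches of 16 and 15 arrays the resultant length was 0.104 and 0.0814. When the arrays were put in 99 random orders, the resultant over all tested probe sets was at or below the real 0.0865 in 81 (median 0.0603), and 44 gave a doubled-angle resultant over all tested probe sets at or above the 0.460 of the real order, so the opposition of 2 groups was not beyond what other orders gave.

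**Figure D2:**
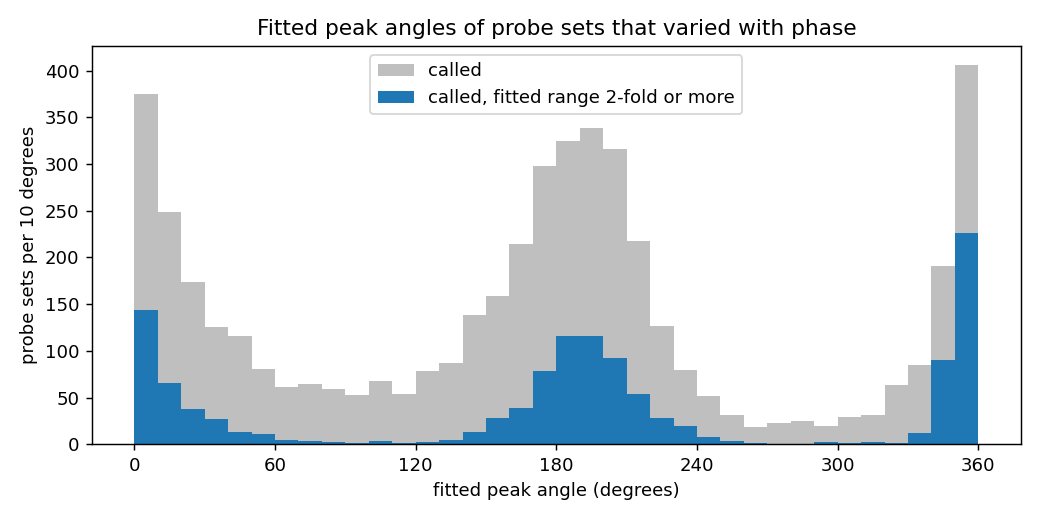
Number of probe sets per 10 degrees (vertical axis) by the fitted peak angle of the first harmonic in degrees (horizontal axis), for the 4831 that varied with phase (grey) and the 1253 of these with a fitted range of 2-fold or more (blue). Of the blue ones, 50.4% peaked from 300 to 60 degrees and 426 from 180 to 240 degrees, against 17 from 60 to 120 degrees. With the first 3 harmonics together 30 and 232 of the same probe sets had their highest point there. With the deposited scale 66.9% peaked from 300 to 60 degrees.

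The third comparison followed 22 gene lists fixed before the data were examined. Ribosome biogenesis genes moved most: their mean varied by 2.52 ± 0.29 on the log2 scale (SE, n = 31 arrays) with a fitted peak at 354.3 ± 6.8 degrees, was highest at 29.67 degrees and lowest at 124.62 degrees. Storage carbohydrate, peroxisomal, chaperone and autophagy genes had fitted peaks on the opposite side of the cycle, with fitted ranges of 1.69, 1.32, 0.93 and 0.92, although their highest arrays lay at 124.62 to 148.35 degrees. Each list mean was tested by 100000 permutations of the arrays, with Benjamini-Hochberg adjustment over the lists, and 21 of 22 lists passed, against 19 with serially correlated arrays and 17 on the deposited scale. In 17 of them the adjusted p was 1.29e-05, from an unadjusted 1e-05 that is the smallest these permutations can give. The fit with serially correlated arrays used the median correlation over single probe sets (0.645). That of the list means was not worked out, so this correction may be too weak for them. For single members, the counts below adjusted over the list alone equalled those adjusted over all probe sets tested in every list except DNA replication and G1/S. Since 89.1% of all probe sets tested passed, a high share of passing members does not by itself mark a list, and several lists lay below that share.

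Among genes of protein synthesis, 77 of 77 measured ribosome biogenesis genes varied with phase, 76 of them by 2-fold or more. The range of the list mean was 1.92 and 3.18 within batches 1 and 2, and its highest and lowest arrays were both in batch 2. NUG1, a GTPase gene of ribosome export, varied by 2.68 ± 0.25 and NOP2, an rRNA methyltransferase gene, by 2.42 ± 0.23 (SE). Cytosolic ribosomal protein genes were high at similar angles but varied less, by 0.44 ± 0.05 in the mean with a fitted peak at 3.1 ± 6.7 degrees and by 0.37 and 0.54 within batches, and 117 of 127 measured members passed. RPS22B varied by 0.94 ± 0.08 and RPL24A by 0.49 ± 0.04 (SE). Many of these genes have near-identical copies whose probe sets may share signal, and RPS17B, RPS19B, RPS23A and RPS29B, named here because their several probe sets disagreed, are uncertain. Mitochondrial ribosomal protein genes were high at other angles, with a mean range of 0.78 ± 0.09 (SE), a fitted peak at 152.3 ± 6.5 degrees, 0.57 and 0.98 within batches and 0.52 on the deposited scale. Of 73 measured members 72 varied, among them RSM26 by 1.08 ± 0.09 and MRPL3 by 0.68 ± 0.06 (SE).

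Sulfur and amino acid synthesis genes also had fitted peaks near 0 degrees and were highest at 41.54 degrees. Sulfur assimilation and methionine synthesis genes varied by 1.17 ± 0.13 in the mean (SE, fitted peak 347.4 ± 6.7 degrees, 0.91 and 1.44 within batches), with 30 of 31 members passing and 20 of them at 2-fold or more. SAM1, which encodes S-adenosylmethionine synthetase, varied by 1.92 ± 0.17 and the cystathionine synthase gene CYS4 by 1.15 ± 0.11 (SE). The genes of other amino acid syntheses varied by 0.69 ± 0.07 (SE, fitted peak 9.3 ± 6.1 degrees, 0.63 and 0.80 within batches), and 60 of 60 measured members passed. The serine hydroxymethyltransferase gene SHM2 varied by 1.71 ± 0.13 and the lysine synthesis gene LYS12 by 1.04 ± 0.08 (SE). Ergosterol synthesis genes did not move as 1 group: 24 of 24 passed, but 14 peaked within 60 degrees of the list mean, which varied by 0.23 ± 0.04 (SE, adjusted p = 0.000165, permutation test, 0.17 and 0.31 within batches) and whose size stood at percentile 60.9 of random lists. ERG4 varied by 1.13 ± 0.09 with a fitted peak at 47.0 degrees and ERG24 by 0.56 ± 0.06 at 303.4 degrees (SE). With median centring the ergosterol list did not pass (range 0.02, adjusted p = 0.851, range of adjusted p over all alternatives 2.44e-05 to 0.851), whereas on the deposited scale its range was 0.39.

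**Figure D3:**
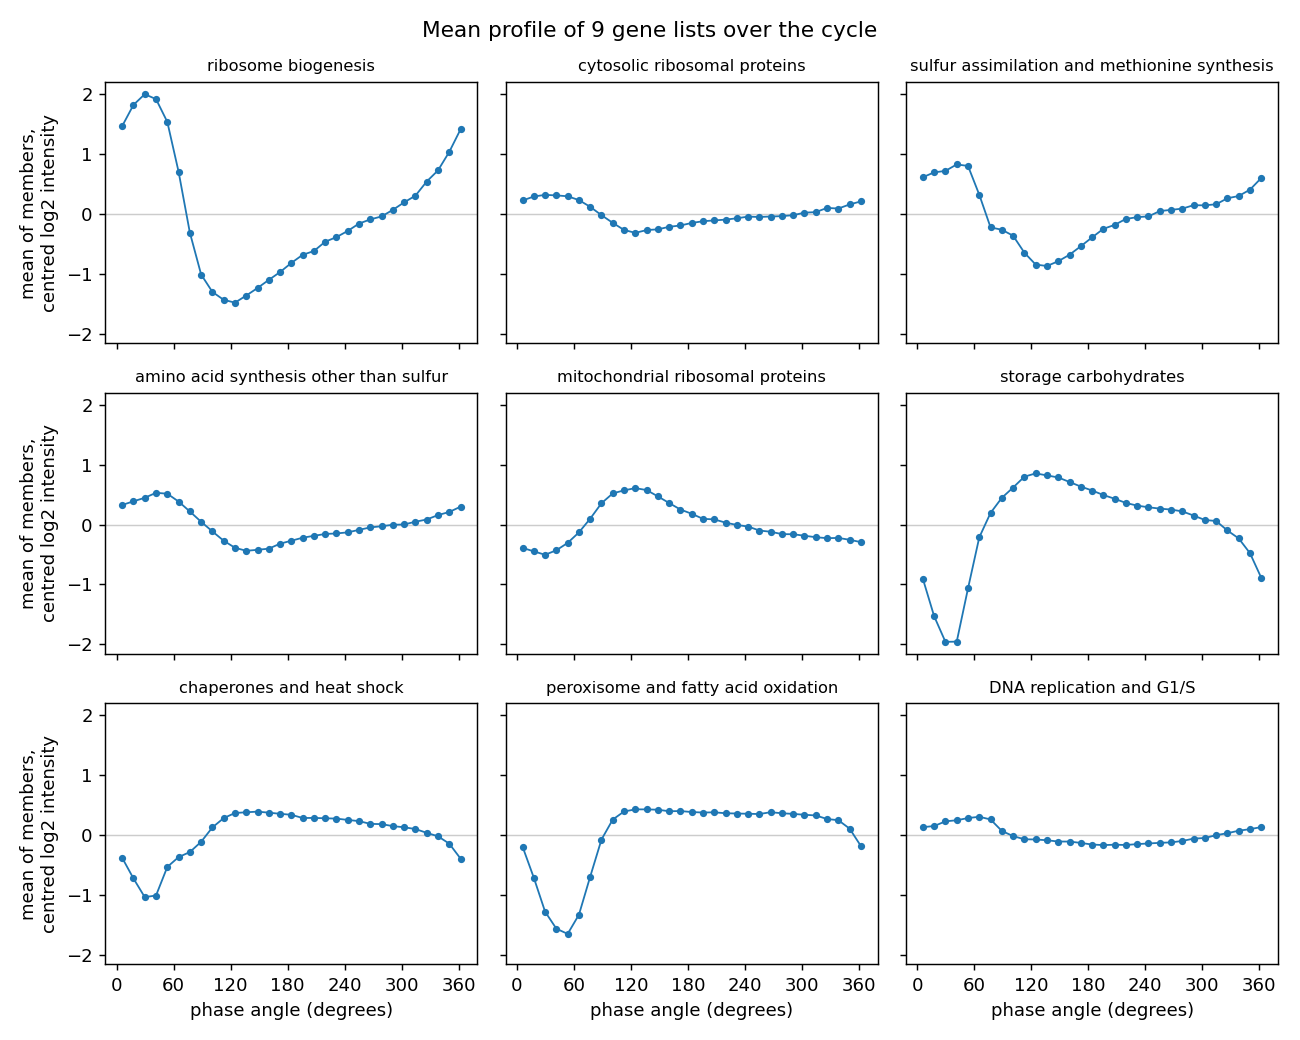
Mean over measured members of centred log2 intensity (vertical axis) against the phase angle in degrees (horizontal axis) for 9 of the 22 gene lists, with 1 point for each of the 31 arrays. Ribosome biogenesis fell from 2.00 at 29.67 degrees to -1.48 at 124.62 degrees, whereas storage carbohydrates ran from -1.96 at 29.67 degrees to 0.85 at 124.62 degrees. The list of peroxisome and fatty acid oxidation genes was lowest at 53.41 degrees with -1.65.

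Genes of carbon reserves and fatty acid oxidation were low near 30 to 60 degrees. Storage carbohydrate genes varied by 1.69 ± 0.26 in the mean (SE, fitted peak 187.8 ± 8.8 degrees, 1.11 and 2.36 within batches), and 17 of 18 passed, 16 of them at 2-fold or more. The glycogenin gene GLG1 varied by 2.24 ± 0.23 and the glycogen synthase gene GSY2 by 2.38 ± 0.25 (SE). Peroxisome and fatty acid oxidation genes varied by 1.32 ± 0.23 (SE, fitted peak 223.1 ± 10.0 degrees, 1.41 and 1.43 within batches), with 26 of 28 members passing. PEX2 varied by 0.56 ± 0.05 with a fitted peak at 220.3 degrees, and PEX21 by 1.68 ± 0.18 on the other side of the cycle at 5.3 degrees (SE).

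Central carbon metabolism moved less as a whole. Nuclear-encoded respiratory chain and ATP synthase genes varied by 0.40 ± 0.07 in the mean (SE, fitted peak 194.9 ± 9.8 degrees, 0.28 and 0.55 within batches), with 37 of 40 passing, and did not pass on the deposited scale (range 0.24, adjusted p = 0.105, range over all alternatives 1.1e-05 to 0.105). The cytochrome oxidase subunit gene COX5B varied by 1.43 ± 0.15 and the cytochrome c gene CYC7 by 2.49 ± 0.32 (SE). Glycolysis and gluconeogenesis genes varied by 0.30 ± 0.08 (SE, fitted peak 193.1 ± 15.1 degrees, adjusted p = 0.000859, permutation test), and 17 of 20 passed, with the hexokinase gene HXK2 at 0.70 ± 0.07 and a fitted peak at 351.5 degrees, and the phosphoglucose isomerase gene PGI1 at 0.53 ± 0.05 and 231.1 degrees (SE). The call for this list was lost on the deposited scale (range 0.17, adjusted p = 0.372), with serially correlated arrays, where the range stayed at 0.32 (adjusted p = 0.0649), and within batch 1 (range 0.15, adjusted p = 0.184), whereas within batch 2 the range was 0.48. The lowest adjusted p over all alternatives was 1.1e-05. Ethanol and acetate genes varied by 0.35 ± 0.07 (SE, fitted peak 199.7 ± 12.1 degrees, adjusted p = 6.95e-05, permutation test, 0.30 and 0.46 within batches), with 12 of 18 passing, and did not pass on the deposited scale (range 0.26, adjusted p = 0.0939, range over all alternatives 1.1e-05 to 0.0939). The pyruvate decarboxylase gene PDC6 varied by 1.48 ± 0.12 with a fitted peak at 21.6 degrees and the aldehyde dehydrogenase gene ALD3 by 2.60 ± 0.25 at 169.4 degrees (SE).

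The TCA and glyoxylate cycle was the list that did not pass. Its mean had a fitted range of 0.22 ± 0.12 (SE, adjusted p = 0.233, permutation test), with 0.05 and 0.45 within batches, although 18 of 19 members passed singly. The mean was not flat: it ran from -0.83 at 41.54 degrees to 0.35 at 100.88 degrees, a span of 1.18, and without the array at 41.54 degrees its fitted range was 0.13 (adjusted p = 0.493). DAL7, a malate synthase gene of allantoin degradation, varied by 3.15 ± 0.22 with a fitted peak at 11.6 degrees, and the peroxisomal malate dehydrogenase gene MDH3 by 1.01 ± 0.14 at 216.3 degrees (SE). The list passed with median centring (range 0.35, adjusted p = 0.00299) and with a linear time trend (range 0.37, adjusted p = 0.0379), against a highest adjusted p of 0.959 over all alternatives. Hexose transport genes varied by 0.35 ± 0.06 in the mean (SE, fitted peak 216.7 ± 9.4 degrees, 0.31 and 0.43 within batches, percentile 84.0 of random lists), with 11 of 13 passing, and by 0.60 over the 6 members left by the stricter filter. HXT3 varied by 0.69 ± 0.05 and HXT8 by 1.21 ± 0.17 (SE), and the close sequence of these transporters leaves their values uncertain.

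Stress and protein turnover genes were low from 0 to 60 degrees and high from 120 to 240 degrees. The chaperone mean was -0.68 from 0 to 60, 0.37 from 120 to 180 and 0.29 from 180 to 240 degrees, and the proteasome mean -0.40, 0.20 and 0.16. All 28 chaperone and heat shock genes varied, their mean by 0.93 ± 0.12 (SE, fitted peak 205.3 ± 7.4 degrees, 0.73 and 1.20 within batches), and 22 of them had fitted peaks from 180 to 240 degrees. HSP30 was among them, whereas SSB2, a chaperone gene of the ribosome, varied by 1.25 ± 0.12 (SE) with a fitted peak at 0.90 degrees. Oxidative stress and thiol redox genes varied by 0.65 ± 0.09 (SE, fitted peak 213.5 ± 7.7 degrees, 0.60 and 0.75 within batches), with 28 of 31 passing. The catalase gene CTT1 varied by 3.30 ± 0.27 with a fitted peak at 200.3 degrees and the oxidoreductase gene OYE2 by 1.04 ± 0.07 at 351.3 degrees (SE). Autophagy and vacuolar protease genes varied by 0.92 ± 0.14 (SE, fitted peak 191.5 ± 8.9 degrees, 0.60 and 1.29 within batches), with 26 of 27 passing, among them ATG22 with 1.12 ± 0.12 at 207.7 degrees and the carboxypeptidase gene CPS1 with 0.58 ± 0.05 at 33.1 degrees (SE). All 33 proteasome genes varied, with fitted peaks from 180 to 240 degrees and a mean range of 0.51 ± 0.07 (SE, 0.39 and 0.66 within batches). SCL1 varied by 0.50 ± 0.06 and RPN11 by 0.56 ± 0.07 (SE).

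Cell division genes varied within a smaller range. DNA replication and G1/S genes varied by 0.39 ± 0.03 in the mean (SE, fitted peak 35.4 ± 4.4 degrees, 0.43 and 0.37 within batches), and 38 of 44 passed, or 37 when adjusted over the list alone. On the deposited scale the range was 0.64. The polymerase epsilon gene DPB2 varied by 1.30 ± 0.07 with a fitted peak at 42.2 degrees and the G1 cyclin gene CLN2 by 1.12 ± 0.08 at 58.2 degrees (SE). M/G1 and daughter-cell genes varied by 0.47 ± 0.04 (SE, fitted peak 198.2 ± 4.5 degrees, 0.50 and 0.44 within batches), with 19 of 19 passing, among them the cell wall gene PIR1 with 0.84 ± 0.04 and the cyclin gene PCL9 with 1.19 ± 0.06 (SE). Histone genes varied by 0.29 ± 0.02 (SE, fitted peak 169.6 ± 3.4 degrees, 0.26 and 0.31 within batches, percentile 73.1 of random lists), with 10 of 10 passing. On the deposited scale this list did not pass (range 0.08, adjusted p = 0.672, range over all alternatives 1.1e-05 to 0.672), nor did HTB2 (0.38 ± 0.04, SE) and HTA1 (0.24 ± 0.03, SE), whose ranges were then 0.28 and 0.06, with adjusted p-values of 0.0696 and 0.780 that were the highest over all alternatives, the lowest being 2.06e-11 and 1.61e-09. G2/M genes varied by 0.15 ± 0.03 (SE, fitted peak 213.2 ± 10.8 degrees, adjusted p = 6.95e-05, permutation test, 0.16 and 0.14 within batches, percentile 43.9 of random lists), with 13 of 20 passing, among them ALK1 with 0.51 ± 0.05 and IQG1 with 0.32 ± 0.05 (SE). This list did not pass with serially correlated arrays (range 0.14, adjusted p = 0.0784, range over all alternatives 1.1e-05 to 0.0784), and on the deposited scale its range was 0.41 with a fitted peak at 302.9 degrees.

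Early meiosis and sporulation genes, included as markers of another developmental state, varied by 0.36 ± 0.05 in the mean (SE, fitted peak 164.3 ± 8.5 degrees, 0.29 and 0.44 within batches, percentile 89.2 of random lists). Of 24 measured members 18 passed, and the fitted peak of the mean moved to 243.7 degrees on the deposited scale. The stricter filter left only 1 member, with a range of 1.32. IME2, a kinase gene of meiotic entry, varied by 1.15 ± 0.11 (SE) at normalized intensities of 96.3 to 331. SPO16 varied by 0.76 ± 0.09 (SE) but did not pass on the deposited scale (range 0.31, adjusted p = 0.265), with the hybridization spikes (range 0.24, adjusted p = 0.269) or with serially correlated arrays, where the range stayed at 0.80 (adjusted p = 0.0555), against a lowest adjusted p of 3.09e-08 over all alternatives.

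The fourth comparison asked which genes changed faster than once per cycle, as terms at 2 and 3 times the phase angle. These terms also pick up a single trough or peak that is not shaped like a cosine. Members of the list for peroxisomes and fatty acid oxidation held 5 of the 10 largest ranges: POT1, the thiolase gene, had a range of 3.16 in these terms (adjusted p = 6.64e-13, limma), the transporter gene PXA2 of 3.12, FOX2 of 3.06, the acyl-CoA oxidase gene POX1 of 3.02 and the peroxisomal catalase gene CTA1 of 2.99. Their profiles had 1 trough between 0 and 120 degrees and were flatter from there on. POT1 averaged 9.94 ± 1.47 (SD, n = 6 arrays) from 0 to 60 degrees and 9.99 ± 1.77 (SD, n = 5 arrays) from 60 to 120 degrees, was lowest at 65.28 degrees with a normalized intensity of 201.8, and averaged 12.47 ± 0.10 (SD, n = 5 arrays) from 120 to 180 degrees. The largest range in these terms belonged to the membrane transporter gene AQR1 with 3.56 (adjusted p = 2.53e-10, limma), whose highest and lowest arrays were at 17.8 and 89.01 degrees. YIG1 with 3.15, FAT3 with 3.04, BDH2 with 2.97 and YNL194C with 2.97 completed the 10 largest.

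With limma, 4669 probe sets (86.1%) passed for these faster terms, 1016 of them with a range of 2-fold or more, and 5188 passed when the first 3 harmonics were tested together. The first harmonic held 60.9% of the variance over all tested probe sets and the first 3 harmonics 89.1%. Within batches 1 and 2, 3417 and 3922 probe sets passed. In simulated data with serially correlated noise, of the spread left after the first 3 harmonics, 59.2% of 5222 flat probe sets passed this test. Of these, 57 had ranges of 2-fold or more. When the arrays were pre-whitened at the correlation of 0.645 used in that simulation, 2524 probe sets passed, among them 954 of the 1016 with 2-fold ranges, and 17 of the flat simulated ones.

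The fifth comparison set the first array, at 5.93 degrees, against the last, at 362.01 degrees, which were taken 1 cycle apart. Few genes differed: 31 probe sets were over 2-fold apart, and of these only SPG1 and YAR009C, named after their values were seen, had a median intensity of 100 or more. SPG1 fell by 1.36 on the log2 scale, from a normalized intensity of 1313 to 513, and YAR009C, part of a Ty1 element, by 1.34. The first array belonged to labelling batch 1 and the last to batch 2, so this pair also compares batches. Over all arrays, beside the first 3 harmonics, batch 2 differed from batch 1 by -0.06 ± 0.14 in SPG1 and -0.01 ± 0.17 in YAR009C (SE, adjusted p = 0.849 and 0.988, limma). The median absolute difference over all probe sets was 0.064 on the log2 scale, smaller than in 27 of 30 pairs of neighbouring arrays, which ran from 0.059 to 0.197. Pairs 15 steps apart differed by 0.217 to 0.581, with 237 to 1583 probe sets over 2-fold apart. Only 1 such pair exists, so the difference has no replicate error and was not tested, and with scaling by the hybridization spikes the difference was 0.104.

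**Figure D4:**
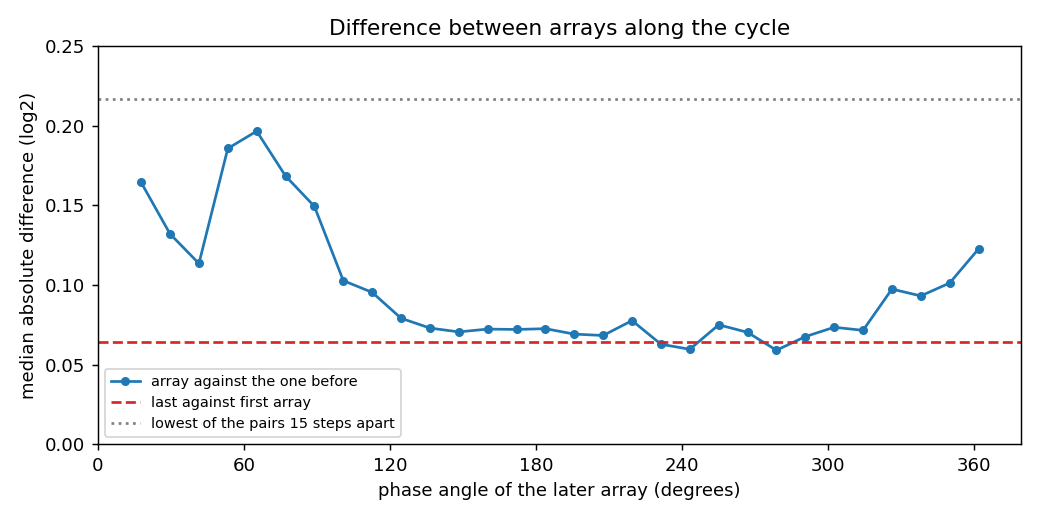
Median absolute difference in log2 intensity over 5422 probe sets (vertical axis) between each array and the one before, against the phase angle of the later array in degrees (horizontal axis). Differences between neighbours ran from 0.059 to 0.197, the last array differed from the first by 0.064 (dashed line), and the least different pair 15 steps apart by 0.217 (dotted line).

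The sixth comparison set odd against even arrays, fitting the 16 arrays of odd and the 15 of even order separately. All 10 genes with the largest ranges passed in both, and the fitted range of AAH1 stayed between 3.20 and 4.98 and that of DBP2 between 3.15 and 4.58 over all alternatives, these among them (adjusted p at most 0.000578 for each, limma). Of the probe sets tested, 4173 passed with odd and 3930 with even arrays, and 3717 with both, against 3025 for independent lists of those sizes. Fitted peaks differed by a median of 3.13 degrees, and 99.3% lay within 30 degrees of each other. Interleaved arrays of 1 culture are not independent cultures, and on the deposited scale 1833 probe sets passed with both.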

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

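The results given here were noticed, and their tests chosen, only after the data were seen. They concern probe sets that entered none of the comparisons, placed on the normalized scale of the other values, and are given as values.

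Some probe sets without a gene in the annotation passed the test for variation with the phase angle. Of 423 without a gene and with a median intensity above the background limit, 48.2% passed limma's F-test. Among these, 73 had a fitted range of 2-fold or more, and the largest was 3.06 on the log2 scale. When adjustment ran over all 3517 probe sets without a gene, 88 passed. As controls, 0 of 88 probe sets for genes outside S. cerevisiae above the same limit passed limma's test (9 had an unadjusted p under 0.05), and 0 of all 1747 did (108 had an unadjusted p under 0.05). By their names 12 of the 423 are reporter controls, of which 6 passed, none with a range of 2-fold or more (largest 0.79); of the other 411, 48.2% passed. What those match was not examined, since no genome sequence was at hand. No pre-whitened fit was made for the probe sets without a gene, and 46.7% of flat simulated probe sets passed under serially correlated noise. Such noise therefore stays open here.

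Of 24 control probe sets for ribosomal RNA, 7 varied with the phase angle, 2 of them by 2-fold or more. The latter, both for the large subunit rRNA of S. cerevisiae, had ranges of 1.08 ± 0.23 and 1.01 ± 0.21 (SE, n = 31 arrays, adjusted p = 0.00211 each, limma) with fitted peaks at 103.6 and 106.4 degrees, whereas another large subunit probe set that passed had a range of 0.63 ± 0.17 (SE, adjusted p = 0.0170, limma) at 233.7 degrees. Probe sets for the small subunit rRNA that passed had ranges of 0.66 ± 0.16, 0.66 ± 0.19 and 0.38 ± 0.12 (SE) with fitted peaks at 206.7, 184.4 and 217.0 degrees. A probe set for the 5.8S rRNA of S. pombe also passed, with a range of 0.76 ± 0.16 (SE) at 146.3 degrees. That for the 5.8S rRNA of S. cerevisiae did not (range 0.15 ± 0.11, SE, adjusted p = 0.540, limma). Probe sets for different parts of 1 rRNA did not all pass or share a phase. No pre-whitened fit was made for these controls either, so serially correlated noise stays open for them too.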

How the results depend on the processing

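Alternatives by labelling batch, by hybridization spike scaling and without the 5 dimmest arrays, pre-whitening at the first-harmonic correlation, and those for odd against even arrays, were chosen after seeing the data, the others before. For distribution of peak phases the resultant length was 0.0870; it was 0.445 on the deposited scale and 0.370 with hybridization spike scaling, and the cause was not tested. Spike scaling also raised the difference of first against last array from 0.064 to 0.104, and on the deposited scale 1833 instead of 3717 probe sets passed with odd and with even arrays; the cause was not tested. With the stricter filter, which tested 3299 probe sets, 3037 passed, 708 of them with ranges of 2-fold or more, and 3044 passed for the faster terms, because fewer genes were tested; all 708 of the 2-fold probe sets still tested passed. The resultant length was then 0.140, and the cause was not tested. With pre-whitening 2919 probe sets passed instead of 4831 and 19 lists instead of 21, and 2524 instead of 4669 passed for the faster terms when pre-whitened at the first-harmonic correlation; the cause was not tested. On the deposited scale 17 lists passed. With the description number as cycle position, 0 probe sets passed limma's test and 0 had 2-fold ranges, while 1383 had an unadjusted p under 0.05. Over all other alternatives for genes that varied with the phase of the oscillation, 3930 (even arrays alone) to 5188 (first 3 harmonics together) passed. With each array left out in turn, 4797 to 4841 probe sets passed, 1152 to 1302 with 2-fold ranges and 4605 to 4689 for the faster terms, the resultant length was 0.0844 to 0.0930, and 21 lists passed each time.

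Of the 1253 probe sets with 2-fold ranges, 1244 still passed on the deposited scale, 1252 with median centring, 1250 with spike scaling, 1174 with pre-whitening and 1246 with a linear trend in time, which moved fitted peaks of the first harmonic most, by up to 58.0 degrees; with the first 3 harmonics together 1250 passed, and the highest point of the curve lay up to 99.2 degrees from the main peak. Named genes kept their side of the threshold in 1321 pairs of gene and alternative, lost a call in 6 and gained one in 2. Lists kept theirs in 298, lost a call in 8 and gained one in 2. The first 3 harmonics together were not among these pairs. Where both fits passed, the largest shift of a fitted peak was 89.6 degrees, for G2/M genes on the deposited scale. Early meiosis genes moved by 79.4 degrees there. Signal over background limited few probe sets, since 76 lay under the limit.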

Other observations

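The gene families and enzyme pairs here, and the tests of labelling batch, serially correlated noise, drift and hybridization brightness, were chosen after the results were seen; the tests with other array orders, of labelling yield and of chance pairing were set before theirs were seen.

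Of 28 gene families looked at by name, several moved as groups that no fixed list describes. The DAL genes, most of which act in allantoin use, had fitted peaks together: 9 of 9 measured members (1 of them in a fixed list) varied with phase, 8 with peaks within 60 degrees of that of their mean, which had a range of 2.05 on the log2 scale and a fitted peak at 20.2 degrees (1.94 and 2.21 within batches 1 and 2), among them the permease genes DAL4 with 3.31 ± 0.23 and DAL5 with 3.02 ± 0.18 (SE, n = 31 arrays). Genes of tRNA modification (DUS and TRM, 18 of 18, mean range 1.77, fitted peak 357.7 degrees, 1.28 and 2.32 within batches) had fitted peaks near that of ribosome biogenesis, with TRM11 at 3.32 ± 0.36 and DUS3 at 3.10 ± 0.37 (SE). Nuclear RNA polymerase subunit genes (25 of 27, mean range 1.54, 1.11 and 2.00 within batches) peaked at 352.9 degrees, but 8 of these are also in fixed lists, and RPB2, RPB3, RPB4, RPB7, RPB9 and RPB11, which belong to polymerase II alone, varied by only 0.07 to 0.59 (RPB4 and RPB11 did not pass), against 1.19 to 3.18 for the others. The purine (ADE, 10 of 10, mean range 0.82, 0.85 and 0.79 within batches) and pyrimidine (URA, 9 of 9, 0.79, 0.66 and 0.93 within batches) synthesis genes peaked at 29.9 and 357.8 degrees. Genes of maltose and isomaltose use (MAL and IMA, 8 of 8, mean range 1.79, 1.58 and 2.12 within batches) peaked at 203.8 degrees, with MAL11 at 2.67 ± 0.30 and MAL31 at 2.48 ± 0.19 (SE), and their members are similar in sequence. All 28 families passed the permutation test (highest adjusted p 0.00163), so that test does not set these 6 apart. Nor does size: they stood at percentile 98.9 (URA), 99.2 (ADE) and 100 (the other 4) of matched random lists, but FMP at 100, SPG at 99.95, MEP, GAP, DUR and AGP at 99.85, PAU at 99.5 and the genes named with a letter before RS at 99.3, and the 6 were picked by hand. No scaling or batch moved their peaks by more than 14.2 degrees. With pre-whitening 7 of the DAL, 16 of the DUS and TRM and 21 of the RNA polymerase genes passed. So did 10 of the ADE, 8 of the URA and 7 of the MAL and IMA genes. Without it 89.1% of all probe sets tested passed, so the full counts above are near what any genes give.

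Some enzymes with the same reaction had fitted peaks on opposite sides of the cycle. Of 20 isoenzyme pairs looked at, both members passed in 15, and in 5 of these the fitted peaks lay over 120 degrees apart. The share of unrelated pairs that far apart was not worked out. Of all probe sets that passed, 23.2% peaked from 0 to 60 and 29.1% from 180 to 240 degrees, so unrelated genes often lie on opposite sides too. The count therefore does not set isoenzymes apart. The transketolase gene TKL1 varied by 0.67 ± 0.05 with a fitted peak at 16.3 degrees and TKL2 by 3.40 ± 0.35 at 208.7 degrees (SE, n = 31 arrays). The hexokinase gene HXK1 varied by 1.15 ± 0.20 at 191.3 degrees, against HXK2 at 351.5 degrees, and the phosphogluconolactonase genes SOL3 and SOL4 by 0.36 ± 0.04 at 355.9 degrees and 3.30 ± 0.39 at 190.6 degrees (SE). These 3 pairs passed and stayed at least 141.4 degrees apart on every scale, within both batches and with pre-whitening. The aminotransferase gene BAT2 (0.47 ± 0.10, SE) did not pass on the deposited scale (range 0.33, adjusted p = 0.0667) or with pre-whitening, where its range stayed at 0.48 (adjusted p = 0.0624), against 1.37e-05 with median centring, the lowest of 6 alternatives. The citrate synthase genes CIT1 and CIT2 are weak, since with pre-whitening neither passed, although ranges stayed at 0.25 and 0.24 against 0.23 and 0.26 (adjusted p = 0.305 and 0.496). CIT1 also did not pass on the deposited scale (range 0.13, adjusted p = 0.522, lowest of 6 alternatives 2.99e-06) or within batch 1 (0.11, 0.304), nor CIT2 with spike scaling (0.23, 0.0596) or within batch 2 (0.20, 0.435). With median centring CIT1 and CIT2 both passed but their peaks lay only 105.8 degrees apart.

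The first pattern weighed is that most probe sets varied with the phase angle. Of 100 orders of the arrays, only 1, the real one, gave as many as 4831 probe sets (highest other 3208). The same held for the 1253 with 2-fold ranges (highest other 774) and the 4669 for the faster terms (highest other 2249). A random order is thus argued against for each count, at 1 of 100 orders. Reordering also breaks the correlation of neighbouring arrays, so it does not bear on serially correlated noise. A labelling batch as the whole source is argued against by 1215 of the 1253 (97.0%) passing within both batches with peaks within 60 degrees, and a drift along the run by the last array differing from the first by 0.064, less than any pair 15 steps apart. Serially correlated noise is argued against as the whole source for the 2-fold probe sets, of which 1174 (93.7%) passed after pre-whitening. Among flat simulated probe sets with 2-fold ranges 13 of 29 (44.8%) also did, so passing does not clear a single probe set. For the 3578 with smaller ranges, of which 1745 (48.8%) passed, noise and phase cannot be told apart. That share lies above the 27.3% (658 of 2410) among flat simulated probe sets of that size that had passed without pre-whitening. It also lies below the 90% asked for to exclude noise. The simulated noise was smaller than the residuals of the first harmonic, so both simulated shares are only a guide. The 2-fold variation may therefore follow the oscillation, which stays a hypothesis, since 1 cycle was sampled and recurrence was not measured.

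The second pattern is that the median deposited intensity of an array varied with the phase angle, by 0.37 on the log2 scale with a fitted peak at 330.1 degrees (permutation p = 0.0134; 0.0141 and 0.214 within batches 1 and 2). Hybridization or scanning brightness is argued against as the whole source, since the medians still varied after the hybridization spikes were subtracted (permutation p = 0.00134, and 0.0165 and 0.0268 within batches). Their range was then 0.25 instead of 0.37 and their fitted peak at 302.9 degrees, so part of the variation went with the spikes. The labelling batch is also argued against as the whole source (permutation p = 0.00903 with batch as a term). Labelling yield is argued against by the medians after subtraction of the poly-A spikes with batch as a term (permutation p = 0.00045). The amounts of spikes added per sample and the scaling by the array software are not stated, so an uneven addition stays open. No biological explanation, such as a changing share of mRNA in total RNA, was tested.

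The third pattern is that neighbouring genes had more similar profiles where they were transcribed away from each other. The median correlation across arrays was 0.21 for 1250 divergent pairs, 0.10 for 2339 tandem pairs, 0.000727 for 1317 convergent pairs and -0.00596 for 4999 random pairs, and 0.21 for the 1238 divergent pairs not in the same fixed list; genes are not independent replicates. Chance pairing is argued against by 10000 shuffles of orientation (one-sided p = 2e-04). Divergent minus random pairs differed by 0.22 (95% bootstrap interval 0.145 to 0.274). Convergent minus random pairs differed by 0.007 (95% bootstrap interval -0.051 to 0.059) and tandem minus divergent pairs by -0.113 (-0.175 to -0.020). Shared 3' ends would raise convergent pairs, and read-through would raise tandem pairs. These differences are contrasts between the same medians that show the pattern. They therefore add no separate test of either cause, and no conclusion on them is drawn. Whether read-through raised tandem pairs over random ones was not tested. No biological explanation was tested.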
